A study of Mus musculus with 18 samples.

How the data were processed

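The series measured chromatin in cardiomyocyte-enriched cell populations of the mouse by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, the 18 libraries fall into 10 groups: for each of 4 targets (G9a, H3K9me2, H3K27me3 and Mef2c) 2 libraries from mice with a floxed G9a gene and the alphaMHC-MerCreMer transgene (here KO) and 2 from mice with the transgene alone (here Cre), plus 1 input library of each genotype. The antibodies were Sigma G6919 for G9a, Abcam ab1220 for H3K9me2, Millipore 07-449 for H3K27me3 and Abcam ab43796 for Mef2c, per the labels. The series text names H3K27me2 at one place where its title and the sample labels name H3K27me3, and the name in the labels was used.

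Per the submitters' processing notes, reads were aligned with BWA 0.7.10-r789 and handled with SAMtools 1.1, and the genome build was mm10 (GRCm38). The authors deposited 4 lists of regions, 1 per target, each comparing KO with Cre. Each listed region has a position, a direction, 4 signal values (2 for Cre and 2 for KO) and a score that is the -log10 p of the authors' own comparison, all 5 numbers held in a single text cell of the deposited lists. The region caller, the scale of the signal values, any normalization and any use of the input libraries are not given in the sources used here, so the values were not treated as counts. The sequencing depth behind them is unknown, and no interval that needs a depth is given. The order of the values (Cre first, then KO) was taken from the name of each list and the sample descriptions, and the values carry no replicate number. The plus sign of a region goes with lower and the minus sign with higher values in KO. The smallest -log10 p in each list was 2, and gaps in the numbers of the regions show that 68.4% of the numbers were kept for G9a, 67.4% for H3K9me2, 74.5% for H3K27me3 and 64.6% for Mef2c. Sequence outside the listed regions has no value, so each share is a share of listed regions. Some regions have a saturated p, given here as such.

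From these values, log2 ratios of the KO mean to the Cre mean were computed with a pseudocount of 1. Regions were called separated where both KO values lay on the same side of both Cre values, which 2 of the 6 orderings of 4 values do (33.3%), though this is not the chance level of regions that were listed because they differ. The smallest exact two-sided p for 2 values against 2 is 0.333, so no single region can pass an exact test. For each target, limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, on log2 of the value plus 1) was fitted over all listed regions, with Benjamini-Hochberg adjustment at 0.05. The authors listed regions because they differ, so these p-values are too small, and they serve only to count the regions that stand out against the spread between libraries. Values that leave out 1 library rest on the assumption that the remaining lone value varies like the others.

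The annotation at hand (GRCm38.p6) gave the span of each gene without strand or exons, and no genome sequence was at hand. The planned windows around gene starts were therefore replaced with windows of 2 kb either side of both ends of each gene span, called gene-end windows here. Exon and intron shares and a planned count of MEF2 motifs could not be computed. A gene was called lower or higher where its gene-end windows touched listed regions of a single direction, and both where they touched regions of each direction. The set tested was 21627 protein-coding genes on chromosomes 1 to 19 and X, and all names in the gene lists matched it.

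The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The 26 lists were fetal and hypertrophy-associated genes, antihypertrophic genes, sarcomere, calcium handling, ion channels and junctions, fatty acid and mitochondrial metabolism, glycolysis, autophagy, cardiac transcription factors, developmental transcription factors that are known Polycomb targets, H3K9 methylation machinery, Polycomb machinery, imprinted genes, germline and pluripotency genes, neuronal genes, fibroblast and matrix markers, endothelial markers, immune markers, smooth muscle and pericyte markers, MEF2 target muscle genes, cell cycle, housekeeping genes, olfactory receptors, vomeronasal receptors, Zfp zinc finger genes and histone cluster genes. Each list was tested for each target and direction with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over all 208 tests. Genes of clustered families are neighbours and not independent. Agreement of targets was tested over genes with Fisher's exact test (24 tests over 6 pairs of targets, adjusted together) and over regions with 1000 circular shifts of 1 list within each chromosome, for which the smallest possible permutation p is 0.001. The net value of a gene was the sum of the listed values in its windows, and the median of a list was placed among 10000 random lists of genes matched on level.

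Named genes were Ehmt2 (the gene of G9a), then in each direction the 10 protein-coding genes with the highest -log10 p in the authors' deposited list that had separated values and regions of 1 direction only, without predicted genes. Nppa, Nppb, Myh6, Myh7, Acta1, Mef2c, Ezh2 and Ehmt1 were followed whatever their values. Up to 4 members with the highest -log10 p were named from the fetal, antihypertrophic, sarcomere, autophagy and developmental lists and from each list past its test. Some genes that this rule selects are not reported here. Members of other lists, and genes named in the closing section, were chosen after their values were seen.

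The limma step was tested on simulated regions drawn from each target's values, with 200 regions changed by known folds. At an unadjusted p under 0.05 it found 38.0% of 4-fold and 79.0% of 16-fold changes for G9a, 50.0% and 88.0% for H3K9me2, 60.0% and 92.0% for H3K27me3, and 41.0% and 88.0% for Mef2c. The simulated spread between replicates was drawn from all regions whatever their level, so these rates need not hold for strong or weak regions. None of the simulated changes passed the adjusted limma p. Only 200 of 504986 to 716658 simulated regions per target were changed, which makes that adjustment hard to pass. The real regions were all listed because they differ, so the simulation cannot tell how many real changes the adjusted threshold misses. The count past that threshold is read with care, with 2 libraries per genotype. The alternatives were a -log10 p of at least 10 or 20, a ratio of at least 2, a length of at least 1000 bp, windows of 1 or 5 kb, gene bodies, a pseudocount of 10, libraries scaled to the same median, limma without its trend, 1 gene kept per shared window, other backgrounds for the list tests, and each library left out in turn. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and numba 0.67.0 did the other computations, and matplotlib 3.10.9 drew the figures.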

Results

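Cardiomyocyte-enriched populations of the mouse heart were profiled by ChIP-seq for 4 targets in 2 genotypes. MerCreMer is a Cre recombinase that becomes active on tamoxifen, here driven by the promoter of Myh6, the gene of the alpha myosin heavy chain. In KO it acted on a floxed Ehmt2, the gene of G9a, which adds methyl groups to lysine 9 of histone H3. H3K9me2 is the product of that reaction and H3K27me3 the mark of Polycomb repressive complex 2, both linked to silent genes, while Mef2c is a transcription factor of muscle. Each target had 2 Cre and 2 KO libraries, and each genotype had 1 input library. Every listed region therefore has 4 values, and the authors' deposited lists hold 621134 regions for G9a, 716658 for H3K9me2, 504986 for H3K27me3 and 534606 for Mef2c. The depth of the libraries is unknown. The listed values summed to between 44305272 (first Mef2c KO library) and 114744154 (first H3K27me3 Cre library) per library, and these sums over chosen regions are not a read depth.

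Ehmt2 (gene ID 110147, chromosome 17, 34898463 to 34914073) was examined first, to see whether signal over the targeted gene differed between the genotypes. G9a signal over the gene went in both directions. In the authors' deposited list the region from 34907251 to 34908750 had G9a values of 410 and 353 in Cre and 67 and 106 in KO, a log2 ratio of -2.13 with a -log10 p of 42.3. The region beside it (34905901 to 34906800) was higher in KO, with 123 and 174 against 175 and 246, a log2 ratio of 0.50. H3K9me2 at one end of the gene (34899001 to 34900050) was higher in KO in that list, with values of 108 and 64 against 322 and 181 and a log2 ratio of 1.54. H3K27me3 at the other end (34913601 to 34914050) had values of 83 and 90 in Cre and 38 and 29 in KO, a log2 ratio of -1.34. The widest Mef2c region (34905101 to 34908450) had values of 1082 and 777 against 830 and 304, so that the KO values did not lie apart from the Cre values. The remaining regions over Ehmt2 were lower for H3K9me2 and G9a (log2 ratio -0.65 for G9a) and went in both directions for Mef2c. By limma, the standard error of the log2 difference was 0.56 for the strongest G9a region and 0.59 for the H3K9me2 region, and the adjusted p was 0.454 and 0.400. The position of the deleted part is not given in the sources used here, so these values check the labels only in part.

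**Figure D1:**
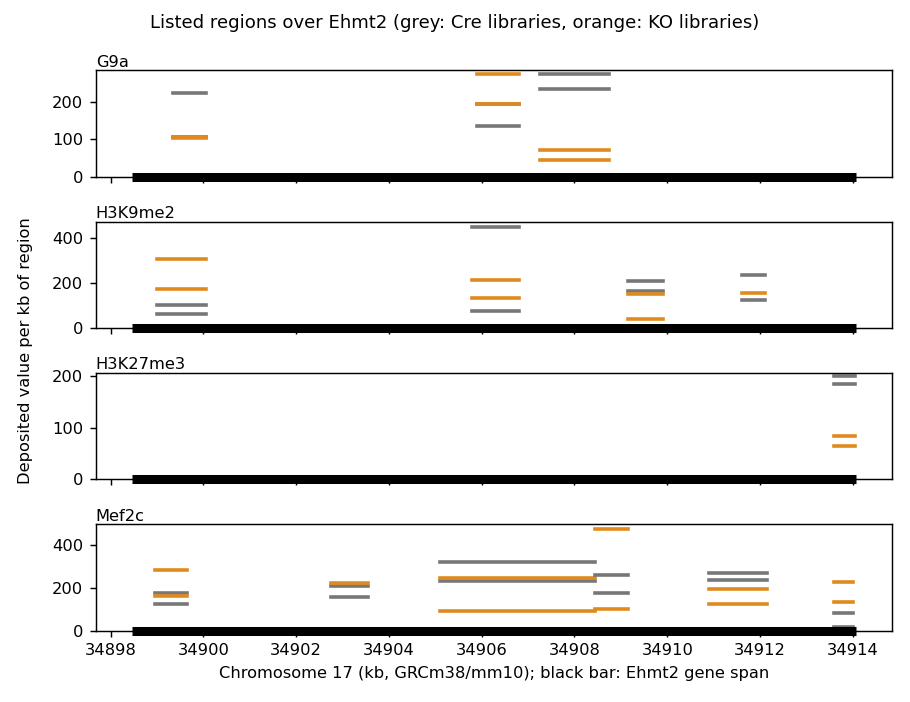
Each line is a listed region over Ehmt2, placed by its position on chromosome 17 in kb and by its deposited value per kb, in grey for the 2 Cre and in orange for the 2 KO libraries, with 1 panel per target and the gene span as a black bar. In the G9a panel both KO lines of the region from 34907251 to 34908750 lie under both Cre lines.

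G9a binding was compared between KO and Cre to ask where the protein was lost. G9a signal was lower in KO at 382008 listed regions (61.5%) and higher at 239126. Across these regions the KO log2 values correlated at r = 0.212 against 0.494 for Cre. In KO 6938 and 22478 values were 0, against 2330 and 1892 in Cre. In each of the 4 lists, r was lower and values of 0 more frequent in the genotype that was lower at most regions. Listing regions because a genotype is low could give this by itself, so these values do not measure library quality apart from that choice. The lower regions with the highest -log10 p near genes covered Smok2a and Smok2b, near-identical kinase genes of the male germline, and the neighbouring ends of Myh6 and Myh7, the genes of the alpha and beta myosin heavy chains. Others lay at Trpm8, the cold-sensing ion channel, at Fndc3a, at Chil3, a secreted chitinase-like protein of macrophages, and at Tcp10c. The 10 genes with the strongest higher G9a regions included Ptpn11, the gene of the phosphatase Shp2, Parg, the enzyme that removes poly(ADP-ribose), and Ifnb1, the gene of interferon beta. In the authors' deposited list the Smok2a and Smok2b region (chromosome 17, 13217651 to 13238350) had values of 6328 and 8474 in Cre and 3466 and 2309 in KO, a log2 ratio of -1.36 with a saturated p. This region lies in a stretch from Smok2a to Tcp10c where summed values of all 4 targets were lower in KO. The Myh6 and Myh7 region of the authors' deposited list (chromosome 14, 54965151 to 54971500) had values of 7256 and 4271 against 3323 and 1738, a log2 ratio of -1.19. Signal per kb there, as a mean over Cre and KO, was 4.66 times the median of the G9a list, and promoters of this transgene type are taken from the sequence between these genes. At Fndc3a (chromosome 14, 72709551 to 72710900) the authors' deposited list gave 315 and 344 in Cre and 8 and 0 in KO, a log2 ratio of -6.05. Trpm8 (-0.91), Erfl (-1.31), Chil3 (-1.30), Tcp10c (-1.01) and Olfr521 (-3.26) had negative log2 ratios in that list. Ptpn11 (chromosome 5, 121192701 to 121193650) had values of 31 and 1 in Cre and 160 and 465 in KO in the authors' deposited list, a log2 ratio of 4.20. Parg (chromosome 14, 32297801 to 32299100) had 57 and 19 against 241 and 438, a log2 ratio of 3.13. Esp34 on chromosome 17 (1.45), Dynlt1b on the same chromosome (3.25), Sbf2 (3.30), Ifnb1 (2.18), Shroom3 (2.43) and Dhrs11 (1.89) were higher in KO. By limma, the standard errors of the log2 differences were 1.26 for Smok2a, 1.15 for Myh6, 1.63 for Fndc3a, 1.49 for Ptpn11 and 0.77 for Parg.

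Among heart genes, G9a signal at Errfi1, a brake on epidermal growth factor receptors, and at the transcription factor Foxo1 was lower in KO. Their log2 ratios were -1.96 and -3.41 in the authors' deposited list, with Pik3ip1, an inhibitor of PI3-kinase, at -2.54. Of the 21 antihypertrophic genes, 9 had lower regions only and 5 higher regions only. The fetal and hypertrophy-associated list had 7 of 19 genes with lower regions only and 2 with higher regions only. In it, the atrial myosin light chain gene Myl7 had a log2 ratio of -1.53, the troponin T gene Tnnt3 -1.74 and the stress-responsive factor Egr1 4.38. Nppb, a natriuretic peptide gene, had regions of both directions, the strongest at -1.12, and Acta1, the skeletal alpha actin gene, also had both. The Cre and KO values overlapped at Nppb, Acta1 and Hoxd13. Mef2c itself (-1.33) was lower and Ezh2, the enzyme of Polycomb repressive complex 2, was higher (1.82). The sarcomere list had 2 lower and 3 higher of 22 genes, with Myom2 at -1.42, Actn2 at 1.78 and Mypn at 1.01. Autophagy genes were lower at 9 and higher at 2 of 28, among them Becn1 (-1.83), Map1lc3b (-2.12) and Ulk2 (-2.22), with Map1lc3a at 1.56. Of 40 developmental transcription factors 8 were lower only and 6 higher only, with Tal1 at -1.74, Nkx6-1 at -1.67, Barhl1 at -2.08 and Hoxd13 at 1.15. Of these lists none passed its Fisher's exact test for G9a. The olfactory receptors did: 423 of 1110 genes (38.1%) had lower G9a regions only, against 26.4% of other genes, an odds ratio of 1.72 with an adjusted p of 1.01e-14. Olfr807, Olfr1111 and Olfr378 had log2 ratios of -3.39, -5.42 and -6.03. These receptor genes lie in clusters and are not independent, and at a -log10 p of at least 10 the odds ratio was 0.940. Other lists gave 6 lower and 3 higher of 22 genes for H3K9 methylation machinery, 8 and 2 of 24 for Polycomb machinery, 5 and 7 of 19 for cardiac transcription factors and 7 and 3 of 19 for calcium handling. Among markers of other heart cells, G9a was lower at 3 and higher at 1 of 20 endothelial markers, at 4 and 3 of 19 immune markers and at 4 and 0 of 12 smooth muscle markers.

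Both KO values lay on one side of both Cre values at 61.5% of G9a regions. For any 4 values 33.3% of orderings do so, but these regions were listed because the genotypes differ, so that figure is not their chance level. The lower share depended on signal: with regions ranked on signal per kb and cut into 5 equal classes, it went from 72.7% in the lowest class to 46.0% in the highest, where higher regions were the more frequent. Scaling libraries to the same median moved the median log2 ratio of all regions by 0.31 for G9a, -0.29 for H3K9me2, 0.28 for H3K27me3 and 0.33 for Mef2c, and left 61.5%, 39.8%, 62.6% and 61.6% of regions lower in KO. The regions were listed because they differ, with median log2 ratios of -1.03 for lower and 0.90 for higher G9a regions. Scaling could therefore hardly change these shares, and their stability is no support for the direction. In limma 0 regions passed the adjusted threshold and 40399 (6.50%) had an unadjusted p under 0.05, of which 31830 were lower and 8569 higher. With libraries scaled to the same median the latter split was 15008 lower and 25831 higher, and without the first KO value 64315 regions passed the adjusted threshold. The unadjusted count was 14859 without the first Cre value, 13085 without the second Cre value, 192875 without the first KO value and 94284 without the second KO value.

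H3K9me2 was compared to ask whether the mark that G9a writes was lost in KO. It was instead higher in KO at 431821 listed regions (60.3%) and lower at 284837. Here Cre, the genotype lower at most regions, had the lower r across regions (0.287 against 0.490 for KO). It also had 6852 and 11938 values of 0 against 2239 and 1786. The strongest higher regions lay at Esp34, a secreted peptide of exocrine glands, at the zinc finger genes Zfp982, Zfp985 and Zfp979, at Tdpoz4, and across the neighbouring ends of Myh6 and Myh7. The strongest lower regions near genes lay at Smok2a and Smok2b and at Nlgn1, a neuroligin of synapses. In the authors' deposited list Esp34 (chromosome 17, 38552951 to 38559250) had values of 609 and 455 in Cre and 2609 and 2674 in KO, a log2 ratio of 2.31 with a saturated p. Esp34 lies within 25 Mb of Ehmt2, a stretch that holds 10.4% of H3K9me2 regions with a -log10 p of at least 50 and 2.04% of all regions. Zfp982 (chromosome 4, 147514101 to 147531100) had values of 7651 and 6164 against 11993 and 13614 in that list, a log2 ratio of 0.89. Across the ends of Myh6 and Myh7 (chromosome 14, 54965051 to 54971450) the authors' deposited list gave H3K9me2 values of 4712 and 2152 in Cre and 6412 and 6252 in KO, a log2 ratio of 0.88. Signal there, as a mean over both genotypes, was 5.46 times the median of the list per kb. Tdpoz4 (1.34), Zfp985 (1.04), Zfp979 (1.05), Nxpe5 (1.99), Elobl (1.07) and Pramel41 (1.29) were also higher in KO. Nlgn1 (chromosome 3, 26333101 to 26334150) had values of 380 and 401 in Cre and 89 and 47 in KO in the authors' deposited list, a log2 ratio of -2.50. Smok2a (-1.61) and Smok2b (-1.18) in the stretch lower in all 4 targets, Rbm12b1 (-1.67), Tspan14 (-5.50), Pclo, the gene of a presynaptic scaffold (-1.94) and the replication gene Mcm5 (-1.55) had negative log2 ratios. By limma, the standard errors of the log2 differences were 0.26 for Esp34, 0.16 for Zfp982, 0.31 for Myh6, 0.55 for Nlgn1 and 0.42 for Smok2a, and the adjusted p was 0.400 for Nlgn1.

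More heart genes had higher than lower H3K9me2 regions only, as did all genes together, and the heart lists did not pass their tests. Of 22 genes of fatty acid and mitochondrial metabolism, 13 had higher H3K9me2 regions only and 4 lower only, an odds ratio of 3.69 with an adjusted p of 0.0630 by Fisher's exact test. Pdk4, which limits glucose oxidation, had a log2 ratio of 1.03, the fatty acid transporter Cd36 1.37, the lipase gene Lpl 1.66 and the coactivator Ppargc1a 1.11. The sarcomere list had 9 higher and 1 lower of 22 genes, with Mypn at 1.25, Ldb3 at 1.76 and Pdlim5 at 2.22. Ion channels and junctions had 10 higher and 3 lower of 22, MEF2 target muscle genes 10 and 2 of 20, and glycolysis 8 and 2 of 18. The antihypertrophic list had 7 higher and 2 lower of 21, with the deacetylase genes Sirt6 (1.78), Sirt3 (2.35) and Hdac5 (1.73) and Foxo1 (1.41). With any 1 value left out, Sirt6 lay between 0.83 and 5.66, Sirt3 between 1.61 and 3.98, Hdac5 between 1.28 and 2.39 and Foxo1 between 0.46 and 5.41. The fetal list had 6 higher and 2 lower of 19, with Tpm2 at 2.39, Nppb at 1.07, Acta1 at 0.98 and Ankrd1 at -1.51, while Nppa, the atrial natriuretic peptide gene, had both directions, the strongest at -1.22. When any 1 value was left out, Tpm2 lay between 1.53 and 4.79, Nppb between 0.30 and 2.83 and Acta1 between 0.26 and 2.48. Ankrd1 lay between -3.29 and -0.73 and Nppa between -2.71 and -0.50. Mef2c was lower (-2.0), while Ehmt1, the partner of G9a, stood at 0.80 with overlapping values, and at 0.18 without the first KO value. Autophagy genes were higher at 8 and lower at 4 of 28, with Lamp1 at 1.97, Sqstm1 at 1.24 and Atg12 at -1.55. Becn1 had a log2 ratio of -1.36, with overlapping values, and 0.23 without the first Cre value. Developmental transcription factors were higher at 10 and lower at 7 of 40, with Hoxa13 at 1.68, Hoxb9 at 1.59 and Olig2 at -1.67. At Hoxa9 both Cre values were listed at 0, with 109 and 82 in KO. Immune markers went the other way, with 7 lower and 2 higher of 19 and an adjusted p of 0.259, while endothelial markers had 1 lower and 7 higher of 20. Olfactory receptors passed: 390 of 1110 (35.1%) were higher only, against 27.8% of other genes, an odds ratio of 1.41 with an adjusted p of 1.15e-05. The call was lost with windows of 5 kb (odds ratio 1.14, adjusted p 0.453) and against genes with a listed region alone (1.13, adjusted p 0.338), within a range of 4.74e-16 to 0.453 over all alternatives. Olfr784 (3.18), Olfr1307 (2.29), Olfr868 (2.26) and Olfr177 (1.96) were among them. Vomeronasal receptors seldom had lower regions only, at 27 of 355 genes, an odds ratio of 0.455 with an adjusted p of 0.000563. Another 155 had both directions, and higher regions only were not more frequent than in other genes (25.6% against 28.2%). Vmn2r80 (2.36), Vmn2r112 (1.1), Vmn1r173 (1.86) and Vmn2r114 (3.10) were higher. Both receptor families are clustered.

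H3K9me2 values lay apart at 65.7% of regions. The share lower in KO went from 31.1% in the lowest of the 5 signal classes to 49.6% in the highest. In limma 0 regions passed the adjusted threshold and 79381 (11.1%) had an unadjusted p under 0.05, with 20682 lower and 58699 higher. With libraries scaled to the same median these were 50300 lower and 29095 higher, so the direction among such regions depends on the scaling. The unadjusted count was 182264 without the first Cre value, 148694 without the second Cre value, 30213 without the first KO value and 30761 without the second KO value.

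**Figure D2:**
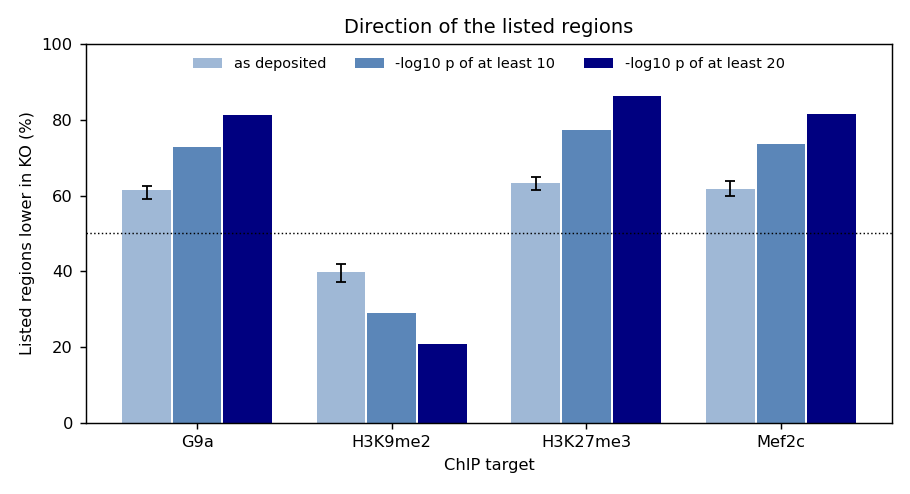
Bars give the percent of listed regions lower in KO for each target, for the lists as deposited and at a -log10 p of at least 10 or 20, with error bars for the range when any 1 value is left out and a dotted line at equal shares. As deposited, G9a stood at 61.5%, H3K9me2 at 39.7%, H3K27me3 at 63.3% and Mef2c at 61.7%.

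H3K27me3 was compared to ask whether the Polycomb mark differed where G9a was deleted. It was lower in KO at 319430 listed regions (63.3%) and higher at 185556, and r across regions was 0.594 between the KO and 0.714 between the Cre libraries. Against this general direction, H3K27me3 was more often higher than in other genes in 3 fixed lists of heart and muscle genes. Of 22 ion channel and junction genes, 11 had higher regions only and 0 lower only (50% against 9.76% of other genes), an odds ratio of 9.24 (95% interval 3.63 to 23.5) with an adjusted p of 8.24e-05 by Fisher's exact test. Of 22 sarcomere genes 9 were higher only and 0 lower only, an odds ratio of 6.39 (2.41 to 16.2) with an adjusted p of 0.00324. Of 20 MEF2 target muscle genes 7 were higher only and 0 lower only, an odds ratio of 4.97 with an adjusted p of 0.0489. That p was 0.184 without the first Cre value, 0.0559 without the second Cre value, 0.130 without the second KO value and 0.0628 with scaled libraries, within a range of 0.00518 to 0.359 over all alternatives. Hcn2, a pacemaker channel gene, had values of 683 and 218 in Cre and 1241 and 1059 in KO in the authors' deposited list (chromosome 10, 79714851 to 79717950), a log2 ratio of 1.35. Dsp, the gene of desmoplakin in the junctions between muscle cells, had 654 and 182 against 1090 and 1041 (chromosome 13, 38150901 to 38153850), a log2 ratio of 1.35. Cdh2, the N-cadherin gene, stood at 1.06 and Kcnh2, a repolarising potassium channel, at 1.13. Without the second Cre value the log2 ratios were 0.75 for Hcn2, 0.70 for Dsp, 0.63 for Cdh2 and 0.64 for Kcnh2, and without the first 2.39, 2.54, 1.69 and 1.87. In the sarcomere list Tcap, a cap of titin, had values of 78 and 165 against 324 and 335 in the authors' deposited list, a log2 ratio of 1.43. Myl2, the ventricular light chain gene, stood at 1.71 with overlapping values (0.70 without the second KO value), Myom2 at 1.42 and Mybpc3, the cardiac myosin-binding protein C gene, at 0.88. Myocd, a coactivator of muscle genes, stood at 2.01 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 1.28. The sarcomere odds ratio was 2.56 with windows of 1 kb (adjusted p 0.349) and 1.18 at a -log10 p of at least 10 (adjusted p 0.941), with the adjusted p between 3.96e-05 and 0.941 over all alternatives.

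**Figure D3:**
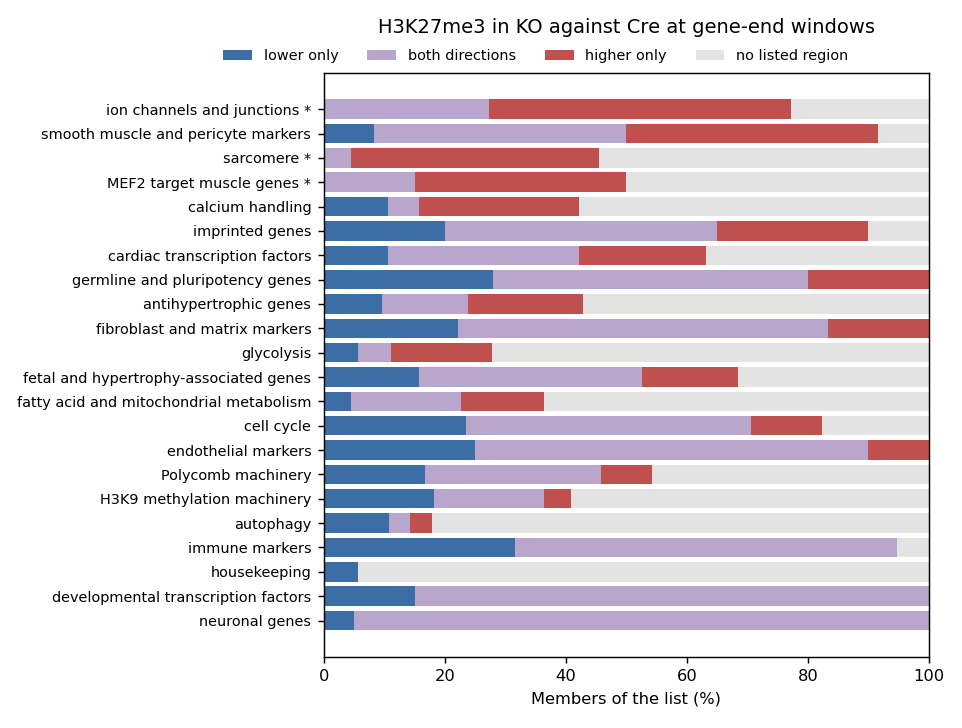
Each bar divides the members of a gene list (percent) by the direction of H3K27me3 regions in their gene-end windows, and an asterisk marks the lists past the Fisher's exact test for higher regions. Of the ion channel and junction genes 50% had higher regions only.

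Markers of other heart cells were counted in the same way. H3K27me3 was lower only at 6 and higher only at 0 of 19 immune markers, among them the leukocyte gene Ptprc (-1.25) and the complement gene C1qa (-0.55). Another 12 had both directions, and lower only (16.5% of other genes) had an adjusted p of 0.608 by Fisher's exact test. Endothelial markers were lower only at 5, higher only at 2 and in both directions at 13 of 20, with Pecam1, an adhesion protein of vessels, at -1.78. Fibroblast markers were lower only at 4, higher only at 3 and in both directions at 11 of 18, and neither of these lists passed its test. Smooth muscle and pericyte markers were higher at 5 and lower at 1 of 12, an odds ratio of 6.59 with an adjusted p of 0.0748. Developmental transcription factors, classic Polycomb targets, were lower only at 6 of 40, higher only at 0 and in both directions at 34. Log2 ratios were small at strongly marked genes: -0.29 at Gata3, -0.32 at Hoxd10 and -0.21 at Hoxa10, which was 0.08 with scaled libraries. Tal1 stood at -0.92. Fetal genes had 3 lower and 3 higher of 19, with Nppb at 1.26, Atf3 at 1.36, Myl4 at 1.67 and Egr1 at -0.73. Acta1 had both directions, the strongest at -1.0. Between Myh6 and Myh7 (chromosome 14, 54968551 to 54969500) values were 1472 and 513 in Cre and 234 and 828 in KO in the authors' deposited list, a log2 ratio of -0.90, and 0.05 without the first Cre value. Antihypertrophic genes were higher at 4 and lower at 2 of 21, with Trim63 at 1.64, Rgs2 at 1.82, Cabin1 at -1.28 and Errfi1 at -1.18. Autophagy genes were lower at 3 and higher at 1 of 28, with Atg14 at -1.33, Wipi2 at -0.76, Atg16l1 at -0.74 and Becn1 at 0.79. Ehmt1 stood at -1.55, and -0.58 without the first KO value. The Cre and KO values overlapped at Ehmt1, Rgs2, Becn1 and Hoxa10 and between Myh6 and Myh7. Olfactory receptors were lower only at 333 of 1110 genes (30% against 15.8%), an odds ratio of 2.28 with an adjusted p of 4.79e-28, among them Olfr552 (-2.47), Olfr212 (-1.50), Olfr521 (-1.20) and Olfr1344 (-1.07), with an odds ratio of 0.960 at a -log10 p of at least 10.

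The strongest higher H3K27me3 regions near genes lay at Grm4, a glutamate receptor gene, at H2-T-ps of the major histocompatibility complex, at Grrp1 and at Zfp536. Lower in rank among the 10 were Six4, a homeobox factor, and Fhod3, a formin that maintains sarcomeres. Grm4 (chromosome 17, 27409951 to 27420600) had values of 1482 and 1093 in Cre and 4135 and 4399 in KO in the authors' deposited list, a log2 ratio of 1.73. Fhod3 (chromosome 18, 24709301 to 24710950) had 101 and 58 against 459 and 696, a log2 ratio of 2.85, and the Six4 region (chromosome 12, 73111501 to 73113950) had 246 and 175 against 983 and 798, a log2 ratio of 2.08. Grm4, H2-T-ps (0.86), H2-Q7 (0.86), Pi16 (1.16) and Vmn1r235 (1.60) lie within 25 Mb of Ehmt2 on chromosome 17. Zfp536 stood at 1.35 and Grrp1 at 1.17. Lower regions lay at Smok2a (-1.03), Tcp10c (-0.97), Lyz2, the lysozyme gene of macrophages (-2.45), Slco2b1 (-1.15), Mpzl3 (-1.19), Ikbke (-0.90), Zfp518a (-0.75) and over Sult4a1 and the neighbouring end of Efcab6 (-0.59). By limma, the standard errors of the log2 differences were 0.20 for Grm4, 0.51 for Fhod3, 0.37 for Six4, 0.44 for Hcn2, 0.48 for Dsp and 0.52 for Tcap.

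In limma 6 H3K27me3 regions passed the adjusted threshold, and 77011 (15.3%) had an unadjusted p under 0.05. Of the 6, 5 lay on chromosome 17, within 25 Mb of Ehmt2, where Gm8909 and H2-T3 sit in the major histocompatibility complex. The region at Gm8909 (36153801 to 36174050) had a limma log2 difference of -2.32 with a standard error of 0.14 and an adjusted p of 0.000416. The region at H2-T3 (36176651 to 36185150) stood at -2.20 with an adjusted p of 0.00880, and another at 36076101 to 36091600 at 1.23 with 0.00880. The region on chromosome 8 (71817551 to 71843650) held Gm5373 and stood at -1.14. Without the first KO value 2 regions passed, and 0 without the first Cre, the second Cre or the second KO value. Their unadjusted counts were 96741, 40280, 33738 and 102247. With adjusted over the list alone p-values, 8 regions of the 22 lists outside the clustered families passed for H3K27me3 and 0 for the other targets, against 0 for each target over all regions. The windows of these lists held 991 regions for G9a, 804 for H3K9me2, 873 for H3K27me3 and 842 for Mef2c. Of them 57, 71, 126 and 96 in that order had an unadjusted limma p under 0.05. Among all listed regions 6.50%, 11.1%, 15.3% and 11.3% did, so the lists held no clear excess. The 8 H3K27me3 regions were higher in KO at Hcn2, Dsp, Hcn4 (0.79) and Irx3 (1.32), and lower at Gja5 (-1.84), Stim1 (-0.88), Tex19.1 (-2.36) and Lyz2 (-2.45). Unadjusted regions were 61884 lower and 15127 higher, and 24677 lower and 40054 higher with scaled libraries. Values lay apart at 67.1% of regions.

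Mef2c binding was compared to ask whether the muscle factor bound differently without G9a. Its signal was lower in KO at 329600 listed regions (61.7%) and higher at 205006, and r across regions was 0.254 between the KO and 0.417 between the Cre libraries. The 10 genes with the strongest lower regions included Smok2a and Smok2b, Crxos, Srgap3, a regulator of Rac, and Rab27a, which moves secretory vesicles. Those with the strongest higher regions included Dach1, a transcription factor, and Tifa, an adaptor of NF-kappaB signalling. In the authors' deposited list the Smok2a region had values of 2107 and 2901 in Cre and 879 and 773 in KO, a log2 ratio of -1.60, in the stretch lower in all 4 targets. Srgap3 had values of 276 and 219 against 4 and 5 in that list, a log2 ratio of -5.50, and Crxos 1053 and 740 against 336 and 105, a log2 ratio of -2.02. Col9a1 (-2.20), Gabrp (-2.22), Rab27a (-2.79), Etfbkmt (-2.12), Slx4 (-3.09), Castor1 (-4.60) and Smok2b (-1.54) had negative log2 ratios. Dach1 (chromosome 14, 97788101 to 97788950) had values of 0 and 4 in Cre and 193 and 204 in KO in the authors' deposited list, a log2 ratio of 6.06. Tifa stood at 2.45, Aldh3b2 at 3.04, Tspo2 at 4.02, Plscr2 at 2.63, Slc35e4 at 3.16, Pym1 at 4.09, Ocel1 at 2.67 and Olfr1446 at 2.86. By limma, the standard errors of the log2 differences were 0.33 for Smok2a, 1.19 for Srgap3, 0.54 for Crxos and 2.12 for Dach1.

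Among heart genes, the Mef2c signal at Myh6 (chromosome 14, 54967201 to 54968000) had values of 1152 and 848 in Cre and 737 and 402 in KO in the authors' deposited list, a log2 ratio of -0.81. The Myh7 region (54968651 to 54970050) stood at -0.56, at 6.42 times the median of the list per kb as a mean over both genotypes. Nppa stood at -1.67, Acta1 at -1.48, Mef2c itself at -1.48, Ezh2 at -2.50 and Ehmt1 at -0.97, while Nppb stood at 0.99. With any 1 value left out, Acta1 lay between -5.21 and -0.44, Mef2c between -2.28 and -0.97 and Ezh2 between -7.75 and -1.52. Ehmt1 lay between -1.84 and -0.43, Nppb between 0.25 and 2.59 and Nppa between -2.05 and -1.37. The Cre and KO values overlapped at Myh7, Acta1 and Wipi1. Of 20 MEF2 target muscle genes 8 had lower Mef2c regions only and 3 higher only, and of 22 sarcomere genes 7 and 5, with Mybpc3 at -2.83, Myom2 at -1.24 and Ldb3 at 1.41. Fetal genes were lower at 7 and higher at 2 of 19, with Tpm2 at -1.49 and Tnnt3 at -1.58. Antihypertrophic genes were lower at 10 and higher at 2 of 21, with Sirt3 at -3.36, Errfi1 at -2.14 and Tsc2 at -1.47. Autophagy genes were lower at 8 and higher at 4 of 28, with Gabarapl2 at -2.12, Sqstm1 at -1.36, Lamp1 at -1.24 and Wipi1 at -1.18, which was 0.14 without the first Cre value. Developmental transcription factors were lower at 13 and higher at 7 of 40, with the neuronal factors Neurog1 at -2.38 and Nkx2-2 at -1.93, Pax7 at 1.60 and Tfap2a at 1.54. Immune markers were lower at 10 and higher at 2 of 19, with an adjusted p of 0.339. None of these lists passed its Fisher's exact test. Olfactory receptors were lower only at 410 of 1110 genes (36.9% against 29.1%), an odds ratio of 1.43 with an adjusted p of 3.49e-06, and odds ratios of 0.793 at a -log10 p of at least 10 and 1.13 with windows of 1 kb (adjusted p 0.349), with Olfr73 at -2.23, Olfr1238 at -5.27 and Olfr384 at -2.17. Vomeronasal receptors seldom had higher regions only, at 27 of 355, an odds ratio of 0.432 with an adjusted p of 0.000162. Another 99 had both directions, and lower regions only stood at 31.5% against 29.5% of other genes. Vmn1r200 stood at -3.09, Vmn2r63 at -2.43, Vmn1r158 at -1.51 and Vmn2r87 at -2.80.

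Other lists did not pass for Mef2c. Germline and pluripotency genes were lower only at 13 and higher only at 1 of 25, with an adjusted p of 0.310. Imprinted genes had 5 lower and 3 higher of 20, neuronal genes 6 and 6 of 20, cell cycle genes 4 and 3 of 17, housekeeping genes 2 and 4 of 18, histone cluster genes 12 and 8 of 71 and Zfp zinc finger genes 108 and 74 of 397. Values lay apart at 65.9% of regions. In limma 0 regions passed the adjusted threshold and 60292 (11.3%) had an unadjusted p under 0.05, of which 46078 were lower and 14214 higher, and 20627 lower and 36957 higher with scaled libraries. The unadjusted count was 26290 without the first Cre value, 30106 without the second Cre value, 100450 without the first KO value and 115017 without the second KO value.

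The targets shared genes in the same direction more often than if they were independent over all genes. Neighbouring genes can share windows and so a region: with 1 gene kept per shared window, 17023 of 21627 remain. The genes are therefore not independent, and the p-values of these tests are too small. G9a and H3K9me2 shared 1129 genes with higher regions only, against 907 under independence. The odds ratio was 1.46 with an adjusted p of 2.09e-19 by Fisher's exact test. These 2 targets also shared 992 genes with lower regions only, an odds ratio of 1.21. G9a and Mef2c shared 2019 lower genes, an odds ratio of 1.39, and 676 higher genes, an odds ratio of 1.51. G9a and H3K27me3 had odds ratios of 1.38 for lower and 1.45 for higher genes, and H3K9me2 and Mef2c 1.30 and 1.49. H3K9me2 and H3K27me3 had 1.18 and 1.29, and H3K27me3 and Mef2c 1.35 and 1.17. The lower genes of H3K9me2 and H3K27me3 had an adjusted p of 0.00220, which was 0.0543 without the second Cre value and between 2.09e-28 and 0.0935 over all alternatives. For opposite directions the odds ratios lay between 0.836 and 1.08. With windows of 5 kb they lay between 1.02 and 1.51, the highest for genes lower for H3K9me2 and higher for Mef2c (adjusted p 4.10e-05), beside 1.51 for genes lower in both. Against genes with listed regions of both targets, genes higher for G9a and lower for H3K27me3 turned from 0.836 to 1.30 (adjusted p 4.49e-05). Over regions that overlap by 1 bp or more, the odds ratio for the same direction lay between 1.56 and 1.82 over the 6 pairs, each with a permutation p of 0.001, the smallest that 1000 shifts can give. The libraries of a genotype could share cells and inputs, which is not given in the sources used here.

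**Figure D4:**
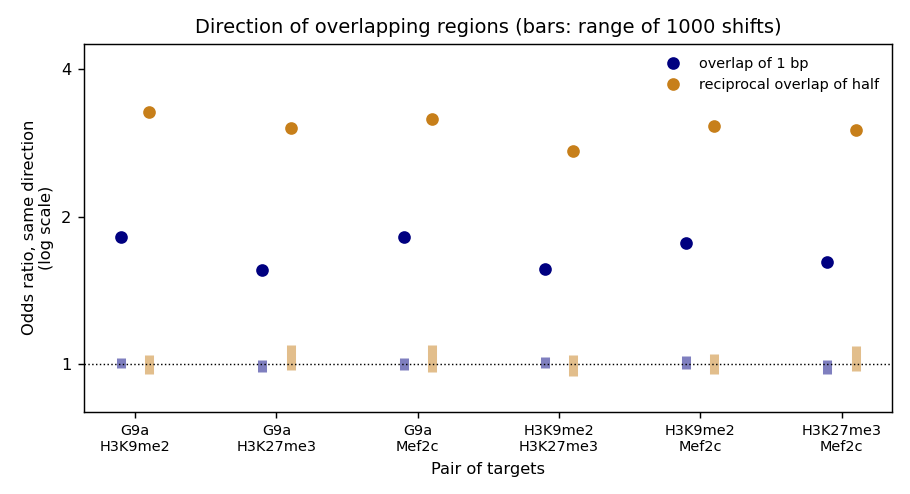
Points give the odds ratio, on a log axis, for overlapping regions of each pair of targets to have the same direction, in blue for an overlap of 1 bp and in orange for a reciprocal overlap of 50%, with bars for the range of 1000 shifts. All 6 pairs lay above the shifted range, from 1.56 to 1.82 at 1 bp and from 2.73 to 3.27 at the reciprocal overlap.

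By chromosome, X was set beside the autosomes without a test. X held few of the listed regions: 0.51% for G9a, 0.67% for H3K9me2, 0.58% for H3K27me3 and 0.36% for Mef2c. G9a was lower in KO at 37.5% of X regions against 61.6% of autosomal regions, and H3K9me2 at 52.0% against 39.7%. At a -log10 p of at least 10 the H3K9me2 share was 43.2% on X and 28.9% over all regions. H3K27me3 stood at 65.1% against 63.2% and Mef2c at 55.8% against 61.7%. Gene-end windows held 5.41% of lower and 5.48% of higher G9a regions, 4.68% and 4.48% for H3K9me2, 5.14% and 6.31% for H3K27me3, and 5.63% and 5.95% for Mef2c, against 5.79% of the genome. Counted over the 21627 genes, 5832 had lower G9a regions only and 3219 higher only. The counts were 3286 and 6096 for H3K9me2, 3580 and 2120 for H3K27me3, and 6384 and 3429 for Mef2c.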

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

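The alternatives that left out a library for genes, gene lists and overlaps, that scaled libraries to the same median for these, that changed the settings of named genes, and the stricter threshold on chromosome X were chosen after the data were seen. No paired analysis was possible because the deposited values carry no replicate number, so the replicate block was not run, and the MEF2 motif alternatives were not run for want of a genome sequence. A minimum mean value of 20 removed nothing. The cause of the differences below was not tested, except that wider windows and gene bodies touch more regions and so more often both directions, and stricter thresholds leave fewer regions. The depth of the libraries is unknown, so what it limits cannot be given. Of the alternatives for the comparisons, 333 left the result the same: a share or count stayed within its set margin, or a test kept direction and side of the threshold. Another 41 moved a share or count beyond its margin without turning its direction. Of the rest, 12 gave more passing results, 23 gave fewer or took a result back, and 3 turned its direction. For other values and named genes, 1013 stayed within the spread, 198 moved and 7 turned.

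The share of regions lower in KO kept its side of 50% under the thresholds, scaling and left-out libraries run, but not by signal: in the highest of 5 signal classes G9a stood at 46.0%. Scaling could hardly turn regions that were listed because they differ, so it is no test of this share. Among regions with an unadjusted limma p under 0.05, scaling turned the more frequent direction in each target. For G9a, H3K9me2, H3K27me3 and Mef2c in that order, the share of regions lower in KO was 72.8%, 28.9%, 77.2% and 73.6% at a -log10 p of at least 10, and 81.3%, 20.7%, 86.2% and 81.6% at 20. It was 67.8%, 33.7%, 68.2% and 66.6% at a ratio of at least 2, and 69.2%, 36.8%, 73.0% and 70.4% for regions of at least 1000 bp. For G9a it lay between 59.1% and 62.5% when any 1 value was left out. The share with values apart was 90.1%, 94.7%, 93.7% and 95.3% at a -log10 p of at least 10, and 56.5%, 61.1%, 59.95% and 60.1% with scaled libraries. The X share of H3K9me2 turned to 43.2% at a -log10 p of at least 10, where that of all H3K9me2 regions was 28.9%.

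In limma, leaving out 1 value gave between 0 and 64315 G9a regions and between 0 and 2 H3K27me3 regions past the adjusted threshold, with unadjusted counts in the report. H3K27me3 had 14 with a pseudocount of 10, 2 with scaled libraries and 0 without the trend, and Mef2c had 1 with a pseudocount of 10.

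With windows of 5 kb, lower and higher genes numbered 3150 and 1711 for G9a, 1384 and 3357 for H3K9me2, and 3579 and 1540 for Mef2c. Over gene bodies they numbered 3330 and 1917, 1905 and 3436, and 3393 and 1805. At a -log10 p of at least 10 there were 1796 higher G9a genes, 1968 lower H3K9me2 genes, and 4182 lower and 1672 higher Mef2c genes.

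List tests passed at 2 for G9a with windows of 1 kb, 4 at 5 kb and 3 against genes with a listed region, and between 1 and 2 when any 1 value was left out. For H3K9me2 they numbered 7 at 5 kb, 4 at a -log10 p of at least 10 and 1 against genes with a listed region. For H3K27me3 they numbered 2 at 1 kb, 7 at 5 kb and 9 at a -log10 p of at least 10, and for Mef2c 4 at 5 kb.

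The list and overlap results below no longer passed their tests, unless a range is given. The H3K27me3 odds ratio of sarcomere genes was 2.56 at 1 kb and 1.18 at a -log10 p of at least 10. That of MEF2 target genes was 3.74 at 1 kb, 2.96 at a -log10 p of at least 10, 4.55 with scaled libraries and 3.64 with 1 gene per shared window, and lay between 3.66 and 4.90 when any 1 value was left out. Olfactory receptors turned at a -log10 p of at least 10, to 0.940 for G9a, 0.960 for H3K27me3 and 0.793 for Mef2c. They no longer passed for H3K9me2 at 5 kb (1.14) and against genes with a listed region (1.13), nor for Mef2c at 1 kb (1.13). Lower Mef2c regions in gene-end windows stood at 1.02 times the genome share with windows of 1 kb, a value without a test. Genes lower in both H3K9me2 and H3K27me3 had an odds ratio of 1.14 at 5 kb and between 1.11 and 1.20 when any 1 value was left out, and genes higher in both had 1.13 at a -log10 p of at least 10.

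With at least 1 choice of a left-out value, the log2 ratio moved by over 1.5 times or turned for 28 of 45 followed genes of G9a, 22 of 50 of H3K9me2, 24 of 54 of H3K27me3 and 27 of 52 of Mef2c. H3K27me3 at Hoxa10 turned to 0.078 with scaled libraries. When any 1 value was left out, H3K27me3 between Myh6 and Myh7 lay between -2.08 and 0.050, H3K9me2 at Becn1 between -3.00 and 0.23, and Mef2c at Wipi1 between -1.86 and 0.14.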

Other observations

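The net values of gene lists and the tests of explanations in this part were chosen after the results were seen. Summed over their windows, genes of fatty acid and mitochondrial metabolism had a median net H3K27me3 log2 ratio of 0.64 against -0.24 for all genes, at percentile 99.4 of random lists matched on level. This rests on the 8 of 22 genes with listed regions, and the Fisher's exact test of the list gave 3 of 22 genes higher only, an odds ratio of 1.45 with an adjusted p of 0.903. Cardiac transcription factors stood at 0.39 over 12 genes (percentile 99.8, adjusted Fisher's exact p 0.608) and calcium handling genes at 0.59 over 8 genes (percentile 97.9, adjusted Fisher's exact p 0.339). These percentiles are not adjusted for the number of lists and targets examined. Lists outside the heart also lay near the ends, such as germline and pluripotency genes for Mef2c (percentile 0.28) and G9a (98.75). Immune markers had a median net H3K9me2 log2 ratio of -0.59 against 0.31 for all genes (percentile 0.130), with 9 of 16 genes negative. Their difference from all genes lay between -0.66 and -0.22 when any 1 value was left out.

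H3K27me3 was higher in KO at sarcomere and ion channel genes, whose joint median net log2 ratio lay 1.12 above that of all genes, but the same genes also stood above all genes for H3K9me2 (by 0.68, percentile 99.3 of random lists) and G9a (by 0.47, percentile 97.3). Without any 1 value, the lowest odds ratio of the 2 lists was 5.14. The regions were still those of the deposited list, chosen with all 4 values in it, and only their direction was called again. A single library as the source can therefore not be excluded. Fewer cardiomyocytes in the KO preparations, which were cardiomyocyte-enriched per the labels, may contribute, but endothelial, immune and fibroblast markers differed from all genes by -0.019, inside the random lists' range (their median of -0.26 lay between -0.35 and -0.09). Smooth muscle and pericyte markers, outside that set, stood 0.33 above all genes, opposite to the fall that fewer cardiomyocytes would give. Their median of 0.09 also lay inside the range of their random lists (-0.56 to 0.12, percentile 96.4). These values neither meet nor exclude the explanation, which keeps it open. A response to the loss of G9a is named by the design and stays open as untested.

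The regions with a -log10 p of at least 50 gathered within 25 Mb of Ehmt2 on chromosome 17, by 2.90-fold for G9a, 5.09-fold for H3K9me2, 3.71-fold for H3K27me3 and 4.46-fold for Mef2c. None of 303 other stretches of 50 Mb held as high a share in any target, so sequence or copies that travel with the floxed allele are a candidate explanation, although the strain label is C57BL/6J. Whether copy number alone accounts for the whole stays open: the targets pointed apart in 24 of 48 bins of 1 Mb there and in 1274 of 1808 on the other autosomes, where the general directions of the lists already set them apart. A copy number difference remains a candidate explanation for Btbd9 to Dnah8 (log2 0.77, 1.24, 0.58 and 0.80 for G9a, H3K9me2, H3K27me3 and Mef2c) and for Smok2a to Tcp10c (-1.26, -0.97, -1.24 and -1.59), with 0.58 the smallest size. Genes named on this part of chromosome 17 may therefore reflect the allele's surroundings, and an effect of G9a itself stays open.

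Signal over listed regions that touch the sequence between Myh6 and Myh7 (chromosome 14, 54968018 to 54970683), and that reach into both genes for G9a, H3K9me2 and H3K27me3, was high, from 4.23 to 6.42 times the list median per kb as a mean over Cre and KO, and lowest by genotype for G9a in KO (399 per kb against a median of 140). Extra copies of the promoter in the MerCreMer transgene, which both genotypes carry, are a candidate explanation, since these regions lay at percentile 99.45 of the list for H3K27me3 and higher for the other targets. A different number of copies in KO and Cre stays open: relative to the medians of their lists the log2 ratios were -0.46 for G9a and 0.17 for H3K9me2, and their difference of 0.62 lay within its standard error of 1.20. High occupancy of the native genes by all 4 targets was not tested and stays open. So does an effect of G9a on the differences between genotypes.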
